A study of Alternaria alternata with 9 samples.

How the data were processed

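Gene expression was measured by RNA sequencing in 9 samples of hyphae of the plant-pathogenic fungus Alternaria alternata grown on medium. Per the labels, 3 samples received 500 µM and 3 received 1500 µM melatonin, an indoleamine derived from tryptophan. The treatment label of the other 3 reads ddH202. As the series' design text gives 0 µM melatonin for a control, it was taken here as water, and the label does not exclude a peroxide. Per the labels' protocols, poly(A) RNA was fragmented, converted to strand-marked (dUTP) libraries and read from both ends on an Illumina instrument. The submitters' processing notes list Bowtie 0.12.2 and the mouse build mm8, which cannot hold these fungal genes. The aligner, the counter and its strand setting for the deposited table are not given in the sources used here.

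The deposited table holds 13577 genes, each with a count and an FPKM value (fragments scaled to gene length and library depth) for each of the 9 libraries, and product, GO and KEGG annotation. All 13577 gene identifiers, starts and ends matched the NCBI RefSeq annotation of the assembly Altal1, so positions are given on its scaffolds, counted from 1. Of these genes 13466 are protein-coding and 111 are tRNA genes or tRNA pseudogenes. An informative product description was present for 5395 genes, 39.7%. The deposited count columns were treated as estimated counts. They hold whole numbers, but in 68 of 68 low values checked the count was the FPKM value times a factor, rounded up, within a tolerance of 0.05. Counts also piled up at multiples of 4: 946 values were 4, against 280 at 3 and 263 at 5. A sequenced fragment therefore stood for about 4 counts, and the deposited counts overstate depth by about that factor. Library totals were 51462124 to 75096525 counts, and the number of fragments was about that divided by 4. The deposited FPKM columns list 1e-04 where a gene had no reads, which was set to 0 here. No genome sequence was used here, so base composition was not examined.

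The test was set before the data were examined as limma on log2(FPKM + 1), with edgeR to take its place if a column held raw counts. By the checks above the count columns hold whole numbers but not raw counts, so this condition was not strictly met. Even so, edgeR 4.0.16 in R 4.3.3 was used as the main test, and limma as first designed is given beside it. The edgeR fit took genes passing filterByExpr (11855 genes), TMM factors and quasi-likelihood F-tests with group as the only term. All 9 libraries were in 1 fit, with Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. Standard errors of log2 fold changes are the absolute fold change divided by the square root of F. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries of a group agreed within sampling noise: the mean chi-square per gene between pairs, on fragments, was at least 125.2. With 3 libraries against 3, an exact permutation test of a single value cannot give a p below 0.1. Exact permutation tests were run on both sides.

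There were 40 gene lists fixed before the data were examined, as patterns on product descriptions. After the descriptions, but not the expression values, had been seen, 14 patterns were narrowed. The pattern for MAP kinase and cAMP signalling, for instance, matched 1341 genes as first written and 20 once narrowed. With at least 5 tested members, 38 lists were tested with camera (limma 3.58.1) on log2(FPKM + 1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The list of conidiation and spore markers had 2 members, and no gene matched the list of mitochondrially encoded and ribosomal RNA. For single genes, the rule fixed beforehand took, where no gene passed the adjusted threshold, the 4 genes with the smallest p in each direction with an informative product, non-overlapping groups and a mean of at least 5 FPKM in the higher group. Gene list members named as examples are those with the smallest p in the direction of the list, or those past the threshold adjusted over the list alone, and were chosen after their values were seen.

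The fit was tested on simulated counts drawn with the means, library sizes and spread of these libraries. For 500 µM against control, in a step on 11855 genes, it called 0 of 50 genes changed 2-fold, 3 of 50 changed 4-fold, 22 of 50 changed 8-fold and 30 of 50 changed 16-fold. For 1500 µM against control the numbers were 0, 4, 21 and 34 of 50, and for 1500 µM against 500 µM they were 1, 3, 19 and 39 of 50. Of 11655 unchanged genes, 2, 8 and 5 were called in the same 3 simulations. The biological coefficient of variation was 0.639. With the dispersion divided by 4 at the same depth, 12 of 50 genes changed 2-fold and 41 of 50 changed 4-fold were called for 500 µM against control. With depth divided by 4 and the dispersion as estimated, 3 of 50 changed 4-fold and 20 of 50 changed 8-fold were called in that comparison, and with depth multiplied by 4 the numbers were also 3 and 20.

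Alternatives set beforehand were other pseudocounts, filters and scalings, a block for the replicate number, sample weights, fits on the compared groups alone, no abundance trend, a 2-fold minimum and each library left out in turn. Alternatives added after the data were seen were DESeq2 1.42.0, counts divided by 4 and other inputs to the list test. Others were controls split 1 against 2 for the agreement of doses, and a fit without library 1 of both melatonin groups. The test first designed, limma on log2(FPKM + 1), was kept as an alternative to edgeR once the columns had been seen. Agreement of the 2 doses was measured on log2 CPM (counts scaled to library depth, prior count 2) and set beside 100 simulations in which no group differed, as was the overlap of genes at an unadjusted p under 0.05. KEGG pathways with at least 10 tested members (102 pathways) were added as a further family of lists after the data were seen. Of 115 genes considered for naming, 22 overlap another gene, 21 of them on the opposite strand, and their values are uncertain if the counting ignored strand. Among genes named in the text these are CC77DRAFT_655232, CC77DRAFT_1020375, CC77DRAFT_1019793, CC77DRAFT_1021580, CC77DRAFT_994655, CC77DRAFT_1097549 and CC77DRAFT_975252, with overlaps of 33 to 225 bases, and on the same strand CC77DRAFT_30145, by 51 bases.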

Results

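Poly(A) RNA of Alternaria alternata hyphae on medium was sequenced without melatonin (control) or with 500 µM or 1500 µM melatonin, with 3 libraries per treatment. The control's treatment label reads ddH202 and was taken as water; if it was a peroxide, each difference from control holds that difference too. The series addresses how melatonin acts in the interaction of this fungus with radish. The question here was what each dose changed in the fungal transcriptome in the absence of the plant. Total counts were 69288293, 58021485 and 53893277 in control libraries 1 to 3. They were 52936840, 51462124 and 51633201 at 500 µM and 66212091, 66122864 and 75096525 at 1500 µM. Between 11653 and 12186 genes had counts in a library, and the 10 most abundant genes took 6.24 to 11.71% of the counts. Values after ± are SDs over the 3 libraries of a treatment.

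Libraries of a treatment resembled each other little more than libraries of different treatments. Across the 11855 tested genes, the mean correlation of log2 CPM (depth-scaled counts) was 0.908 within treatments (9 pairs) and 0.899 between treatments (27 pairs). Grouping by treatment took up 28.5% of the total variance, a share of which any grouping of the libraries would take part. Of the 280 ways to part the 9 libraries into 3 groups of 3, 64 gave a pseudo-F at least as large as the labels did (1.20, exact permutation p = 0.229). The first principal component (30.5% of variance) placed control libraries 2 and 3 and 1500 µM libraries 2 and 3 on one side. Control library 1, 1500 µM library 1 and the 3 libraries at 500 µM lay on the other side. The library nearest to a given library belonged to its own treatment for 4 of the 9.

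**Figure D1:**
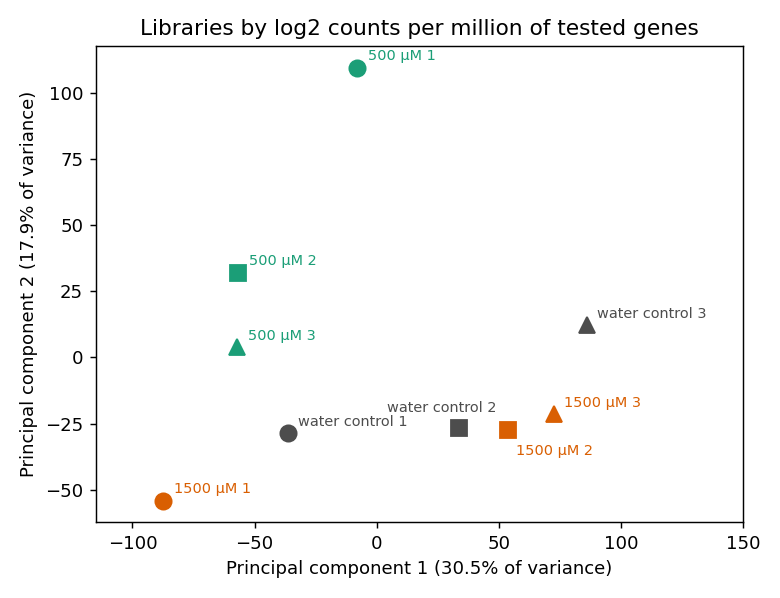
Position of the 9 libraries on the first (x axis, 30.5% of variance) and second (y axis, 17.9%) principal components of log2 CPM (depth-scaled counts), with colour for treatment and symbol for library number. 1500 µM library 1 (-87.5 on the first component) lay far from 1500 µM libraries 2 (53.9) and 3 (72.4).

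At 500 µM melatonin, gene lists of the translation machinery and of respiration had lower means than in the control. Lists of fatty acid oxidation and nitrogen uptake had higher means. For ribosome biogenesis, mitochondrial ribosomal proteins and nitrogen uptake, libraries at 500 µM and control libraries overlapped. Of the 55 cytosolic ribosomal proteins tested, 53 had a lower mean at 500 µM. The list mean was 7.66 ± 0.52 on the log2(FPKM + 1) scale (SD, n = 3) against 8.76 ± 0.26 in controls, a difference of -1.10. Every library at 500 µM lay below every control library (exact permutation p = 0.1, the smallest that 3 against 3 allows). Other lists were separated in the same way, among them antioxidant enzymes and fatty acid synthesis, which did not pass by camera. By camera 8 of the 38 lists passed the threshold, 6 lower and 2 higher. None of the 8 passed with an estimated correlation (adjusted p = 0.728 for each), nor with fry, where the smallest adjusted p was 0.214.

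Among ribosomal proteins, 30 of 55 were past the threshold when adjusted over the list alone, all lower, with log2 fold changes of -1.69 to -1.05, and 0 when adjusted over all genes. Ribosomal protein L24 (CC77DRAFT_932848) averaged 323 ± 131 FPKM at 500 µM and 973 ± 173 FPKM in controls. Ribosomal protein L22e (CC77DRAFT_984414) averaged 157 ± 78.2 FPKM and 487 ± 110 FPKM. The list of ribosome biogenesis factors was lower by a mean log2 difference of -0.85 (29 of 30 members lower, camera adjusted p = 0.000109), mitochondrial ribosomal proteins by -0.62 (11 of 11, 0.00182) and translation factors by -0.51 (25 of 28, 0.000168). Control library 3 carried much of these differences. Without it they were -0.13 for ribosome biogenesis, -0.37 for mitochondrial ribosomal proteins and -0.26 for translation factors, and none of the 3 lists passed. The mitochondrial list also did not pass without 500 µM library 2 (-0.405). For ribosome biogenesis the control mean was 4.53 ± 1.24 against 3.69 ± 0.71 at 500 µM. The exact permutation p was 0.5 for ribosome biogenesis, 0.2 for mitochondrial ribosomal proteins and 0.1 for translation factors. In these 3 lists no member passed the threshold over all genes or over the list alone. Respiratory chain and ATP synthase genes differed by -0.44 (25 of 31 lower, camera adjusted p = 3.11e-05). The NADH dehydrogenase iron-sulfur protein 3 precursor (CC77DRAFT_1020506) averaged 69.1 ± 26.6 FPKM against 131 ± 0.78 FPKM. Amino acid synthesis differed by -0.51 (45 of 55 lower, camera adjusted p = 8.26e-05). In that list homocitrate synthase (CC77DRAFT_1052185), the entry enzyme of fungal lysine synthesis, averaged 91.0 ± 6.58 FPKM against 388 ± 240 FPKM. In neither of the last 2 lists did a member pass over all genes or over the list alone, and the exact permutation p of each was 0.1.

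Fatty acid oxidation and peroxisome genes were higher by a mean log2 difference of 0.44 (24 of 32 members higher, camera adjusted p = 0.00182, adjusted p = 0.728 with an estimated correlation, exact permutation p = 0.1). No member passed over all genes or over the list alone. A carnitine acetyltransferase-like gene (CC77DRAFT_1064255), of the family that shuttles acetyl units between organelles, averaged 370 ± 213 FPKM at 500 µM and 62.7 ± 34.1 FPKM in controls. 3-Ketoacyl-CoA thiolase 1 (CC77DRAFT_1021580), which cleaves acetyl-CoA from the acyl chain, averaged 188 ± 92.6 FPKM and 66.7 ± 21.1 FPKM. Nitrogen uptake and nitrate use was higher by 0.25 (52 of 77 higher, camera adjusted p = 0.0182, exact permutation p = 0.2). It did not pass with quantile normalization, without control library 3 (mean 0.18) or without 500 µM library 2 (0.20). Its 2 members past the threshold over the list alone were an amidase (CC77DRAFT_871709) and a putative amino acid transporter (CC77DRAFT_1067930, 62.4 ± 70.7 FPKM against 5.37 ± 2.15 FPKM), and 0 passed over all genes.

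**Figure D2:**
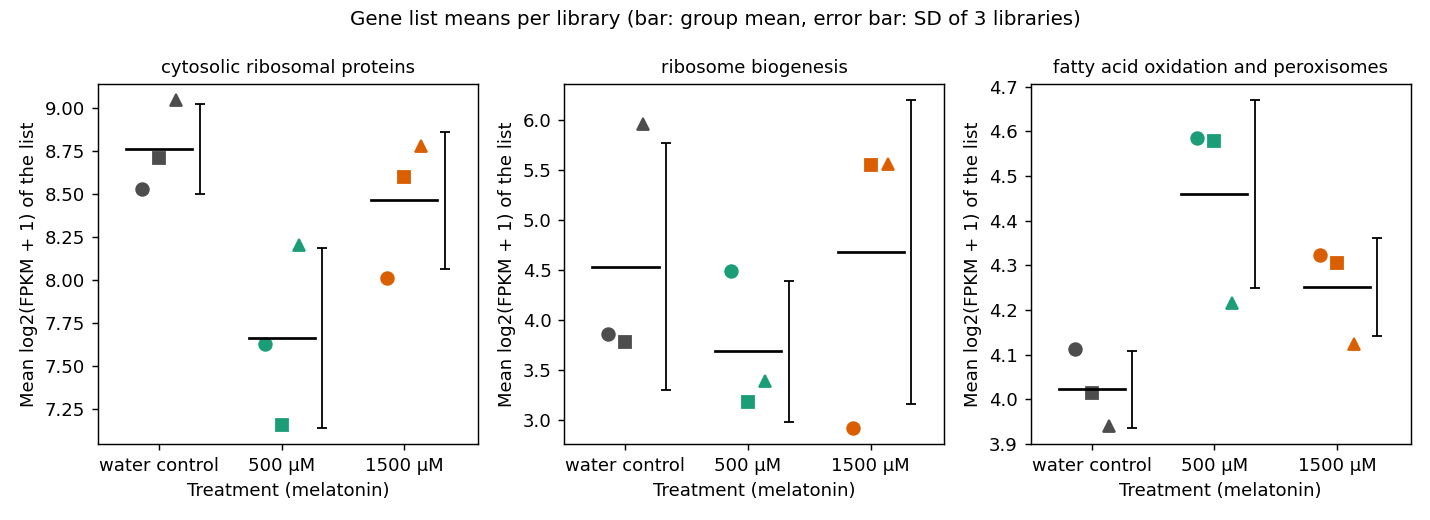
Mean log2(FPKM + 1) over the members of 3 gene lists (y axis) in each library by treatment (x axis), with symbols for library numbers, bars for treatment means and error bars for the SD of 3 libraries. Cytosolic ribosomal proteins averaged 8.76 in controls and 7.66 at 500 µM, and 1500 µM library 1 (8.01) lay nearer the 500 µM libraries than 1500 µM libraries 2 and 3 did.

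No single gene passed the adjusted threshold between 500 µM and control in edgeR's quasi-likelihood test (0 of 11855, smallest adjusted p = 0.123). At an unadjusted p under 0.05 there were 936 genes, 439 higher and 497 lower, where chance gives about 593. DESeq2 called 118 genes (61 higher, 57 lower) and limma on log2(FPKM + 1) called 0. The treatments did not overlap for 13.3% of the tested genes, where chance gives 10%. The genes below have adjusted p of 0.556 in edgeR and are thus not past the threshold. All 8 of them were among DESeq2's calls. Genes passed in edgeR without control library 1 (2 genes), 1500 µM library 2 (1 gene) or 1500 µM library 3 (1 gene).

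Among genes with higher values at 500 µM, phosphoenolpyruvate carboxykinase (CC77DRAFT_1021809, NW_017306203.1, 472043 to 474851), which commits carbon to gluconeogenesis, averaged 1832 ± 795 FPKM against 307 ± 141 FPKM in controls, a log2 fold change of 2.54 (SE 0.56). Mitochondrial uncoupling protein 2 (CC77DRAFT_30145, NW_017306190.1, 1421396 to 1423285) averaged 323 ± 148 FPKM against 60.9 ± 25.9 FPKM (2.41, SE 0.50). The amidase CC77DRAFT_871709 (NW_017306198.1, 1100148 to 1102602) averaged 23.1 ± 8.76 FPKM against 5.26 ± 0.84 FPKM (2.05, SE 0.41). A potassium transporter (CC77DRAFT_947768, NW_017306218.1, 107081 to 109638) averaged 67.4 ± 53.8 FPKM against 4.77 ± 3.27 FPKM (3.87, SE 0.86). Among genes with lower values, an aldo/keto reductase (CC77DRAFT_394570, NW_017306211.1, 318767 to 320151) averaged 95.1 ± 16.8 FPKM against 967 ± 440 FPKM (-3.45, SE 0.82). A GroES-like protein (CC77DRAFT_995685, NW_017306208.1, 331769 to 333222) averaged 5.48 ± 2.55 FPKM against 24.4 ± 6.68 FPKM (-2.17). A DJ-1/PfpI family gene (CC77DRAFT_1096335, NW_017306203.1, 931736 to 932553) averaged 8.46 ± 3.94 FPKM against 45.6 ± 25.1 FPKM (-2.44), and an NAD(P)-binding protein (CC77DRAFT_1061325, NW_017306199.1, 668100 to 669009) 3.90 ± 0.68 FPKM against 24.4 ± 11 FPKM (-2.71).

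Members of other lists were past the threshold only when adjusted over the list alone, with 0 over all genes, and those lists did not pass by camera. The glyoxylate cycle, which lets fungi build sugars from acetyl units, held 2 of these among 20 genes of the tricarboxylic acid and glyoxylate cycles (camera adjusted p = 0.0933). Isocitrate lyase (CC77DRAFT_926396) averaged 953 ± 700 FPKM against 113 ± 79.2 FPKM, and glyoxysomal malate synthase (CC77DRAFT_1056777) 470 ± 275 FPKM against 98.6 ± 36.1 FPKM. Glycolysis and gluconeogenesis held 3 of 27 (camera adjusted p = 0.885), namely phosphoenolpyruvate carboxykinase, an alcohol dehydrogenase (CC77DRAFT_72145, 105 ± 21.3 FPKM against 44.1 ± 1.17 FPKM) and an alcohol dehydrogenase-like gene (CC77DRAFT_318167). Melanin synthesis and laccases held 1 of 8, a laccase-1 precursor (CC77DRAFT_1044227, 45.6 ± 43 FPKM against 3.74 ± 3.20 FPKM). Cytochrome P450 held 1 of 95, CC77DRAFT_1083238, with no reads in any control library and 3.04 ± 1.90 FPKM at 500 µM. Sugar transporters held 1 of 25, CC77DRAFT_975252 (2.79 ± 0.29 FPKM against 0.57 ± 0.02 FPKM).

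**Figure D3:**
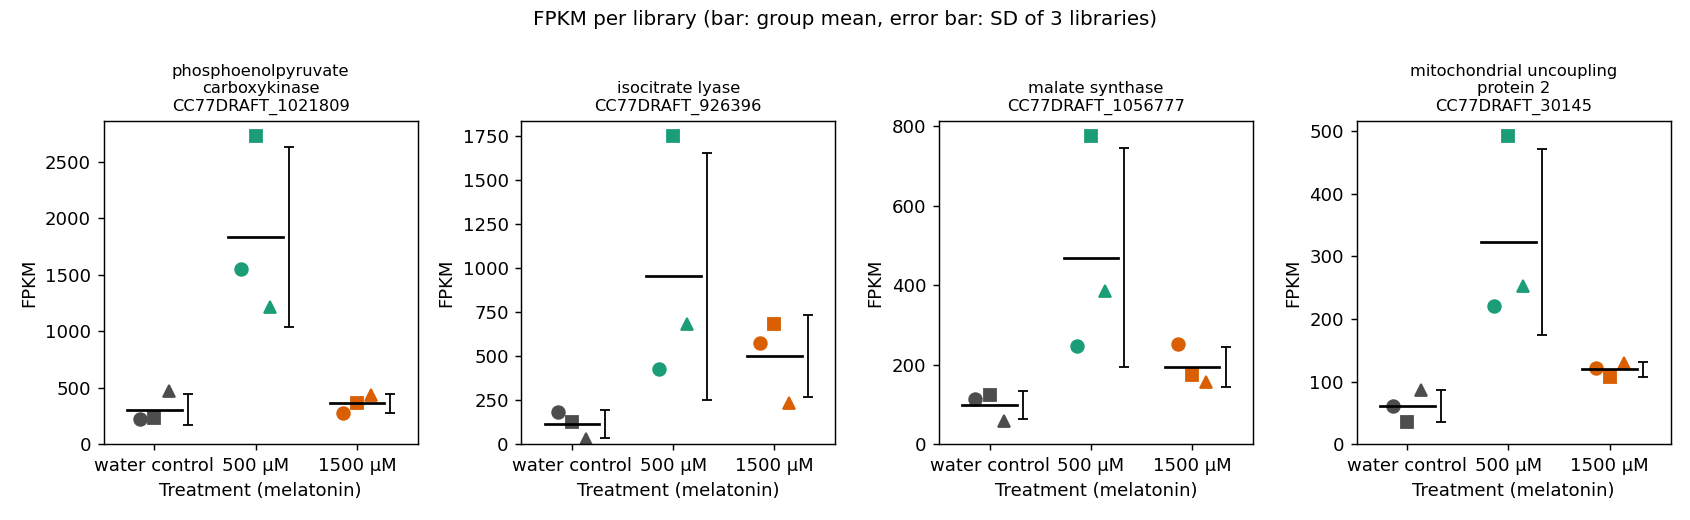
FPKM (y axis) of 4 genes of gluconeogenesis, the glyoxylate cycle and mitochondrial uncoupling in each library by treatment (x axis), with symbols for library numbers, bars for treatment means and error bars for the SD of 3 libraries. In each panel the 3 libraries at 500 µM lay above the 3 control libraries, and none of these genes passed the threshold adjusted over all genes.

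The ribosomal protein, respiratory chain, amino acid synthesis and fatty acid oxidation lists stayed past the camera threshold with every library left out in turn. Without control library 3 only these 4 of the 8 lists passed, and glutathione S-transferases, not called with all libraries in, passed as lower (camera adjusted p = 0.00971), which makes 5. Without control library 1 it was 13, and without 500 µM library 3 it was 15. Passing with libraries left out does not tie a list to treatment, since camera with the preset correlation also passed the ribosomal list in mixed splits. With control library 1 and 500 µM library 3 exchanged, ribosomal proteins had a camera adjusted p of 4.95e-28, against 1.78e-28 with the labels.

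At 1500 µM melatonin, most of the lists past the camera threshold were lower than in controls by less than 0.5 on the log2 scale, and none of these calls held without 1500 µM library 1. The 9 lists comprised 8 lower and 1 higher. Cytosolic ribosomal proteins differed by -0.30 (48 of 55 lower, camera adjusted p = 0.00115), respiratory chain and ATP synthase genes by -0.29 (27 of 31, 0.00115) and tubulin, actin and motor genes by -0.32 (24 of 29, 0.00207). DNA replication and cell cycle genes differed by -0.27 (29 of 40 lower, 0.00481), and amino acid synthesis by -0.30 (40 of 55, 0.00628). Fatty acid oxidation and peroxisome genes were higher by 0.23 (22 of 32 higher, 0.0253). With an estimated correlation the adjusted p was 0.976 for each of the 9 lists, and with fry the smallest adjusted p was 0.991. The exact permutation p was 0.5 for ribosomal proteins, 0.2 for the respiratory chain, 0.4 for DNA replication and 0.6 for amino acid synthesis. For tubulin, actin and motor genes and for fatty acid oxidation it was 0.1, the smallest possible. Without 1500 µM library 1, which lay apart from libraries 2 and 3, none of the 9 lists passed. For most of them the difference itself shrank, to -0.075 for ribosomal proteins, -0.12 for the respiratory chain, -0.15 for tubulin, actin and motor genes and -0.13 for DNA replication, and it reversed to 0.051 for amino acid synthesis. For fatty acid oxidation it was 0.19, close to the value with all libraries. Instead 4 others passed, all higher at 1500 µM, namely antioxidant enzymes (camera adjusted p = 0.0119), ribosome biogenesis (3.71e-12), translation factors (0.000637) and heat shock proteins and chaperones (0.000637). Without control library 3 the lists past the threshold were tubulin, actin and motor genes (0.0426) and, higher at 1500 µM, ribosome biogenesis (3.96e-07). Without control library 3 ribosomal proteins differed by -0.16 and DNA replication by -0.12. Without 1500 µM library 3 ribosomal proteins differed by -0.46 and amino acid synthesis by -0.51. With sample weights none of the 9 passed. Fatty acid oxidation also did not pass without control library 1 (0.27), 1500 µM library 2 (0.20) or 1500 µM library 3 (0.29), though its difference stayed between 0.19 and 0.29 with each library left out.

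Lower means at 1500 µM were also recorded for 3 lists, of ergosterol synthesis, fatty acid synthesis, and metal and phosphate homeostasis. Ergosterol synthesis, which makes the main fungal membrane sterol, differed by -0.46 (8 of 11 lower, camera adjusted p = 0.0187). Its early enzyme hydroxymethylglutaryl-CoA synthase (CC77DRAFT_1017717, NW_017306193.1, 1390878 to 1393075) averaged 51.1 ± 11.3 FPKM against 207 ± 138 FPKM in controls, and was the 1 member past the threshold over the list alone. Farnesyl pyrophosphate synthetase (CC77DRAFT_1048567) averaged 21.6 ± 10.7 FPKM against 86.9 ± 83.6 FPKM. Fatty acid synthesis differed by -0.62 (5 of 5 lower, 0.0235), with ATP-citrate synthase (CC77DRAFT_784023), a source of cytosolic acetyl-CoA, at 108 ± 75.8 FPKM against 220 ± 19.3 FPKM. Metal and phosphate homeostasis differed by -0.49 (13 of 18 lower, 0.0253), with a phosphate permease (CC77DRAFT_927224) at 14.1 ± 2.96 FPKM against 50.1 ± 36.4 FPKM. All 3 lists had an adjusted p of 0.976 with an estimated correlation. The exact permutation p was 0.2 for ergosterol synthesis, 0.5 for fatty acid synthesis and 0.4 for metal and phosphate homeostasis. Without 1500 µM library 1 fatty acid synthesis differed by -0.069, metal and phosphate homeostasis by -0.19 and ergosterol synthesis by -0.34. Without control library 3 the differences were -0.38, -0.24 and -0.53, and without 1500 µM library 3 fatty acid synthesis differed by -1.003. Ergosterol synthesis did not pass without control library 2 (-0.29) or 1500 µM library 3 (-0.44), nor fatty acid synthesis without control library 2 (-0.67). In no list did a member pass over all genes.

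Between 1500 µM and control, edgeR called 0 of 11855 genes (smallest adjusted p = 0.665). At an unadjusted p under 0.05 there were 369 genes, 160 higher and 209 lower, where chance gives about 593. DESeq2 called 28 genes (19 higher, 9 lower) and limma on log2(FPKM + 1) called 0. The treatments did not overlap for 6.1% of the genes, where chance gives 10%. Genes passed in edgeR without control library 1 (2 genes), 1500 µM library 1 (1 gene), 1500 µM library 2 (1 gene) or 1500 µM library 3 (2 genes). The following genes had edgeR adjusted p of 0.665 or 1 and were not past the threshold.

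An NAD(P)-binding protein (CC77DRAFT_1021879, NW_017306203.1, 698095 to 699162) averaged 128 ± 21.9 FPKM at 1500 µM against 34.5 ± 10.3 FPKM in controls, a log2 fold change of 1.92 (SE 0.36). A general substrate transporter of the major facilitator family (CC77DRAFT_1067280, NW_017306224.1, 38552 to 40456) averaged 59.8 ± 17.3 FPKM against 12.8 ± 4.77 FPKM (2.25, SE 0.43). An epoxide hydrolase-like gene (CC77DRAFT_801013, NW_017306197.1, 124633 to 126120) averaged 175 ± 38.8 FPKM against 58.3 ± 6.93 FPKM (1.60, SE 0.35). A clavaminate synthase-like gene (CC77DRAFT_314509, NW_017306191.1, 1040061 to 1041615) averaged 71.5 ± 53.5 FPKM against 6.93 ± 2.06 FPKM (3.36, SE 0.81). The DJ-1/PfpI family gene CC77DRAFT_1096335, also listed at 500 µM, averaged 9.10 ± 3.26 FPKM against 45.6 ± 25.1 FPKM (-2.31). A putative GPI-anchored dioxygenase (CC77DRAFT_655232, NW_017306193.1, 1453908 to 1455770) averaged 1.32 ± 0.78 FPKM against 9.19 ± 8.86 FPKM (-2.88). A gene with an FAD-binding domain (CC77DRAFT_533302, NW_017306192.1, 1033780 to 1036040) averaged 5.83 ± 4.62 FPKM against 34.4 ± 18.6 FPKM (-2.55). With hydroxymethylglutaryl-CoA synthase, 6 of these 8 genes were among DESeq2's calls. A high-affinity glucose transporter (CC77DRAFT_1023430) was past the threshold over the sugar transporter list alone, at 840 ± 398 FPKM against 155 ± 51.1 FPKM. The cytochrome P450 gene CC77DRAFT_1083238 was also past it over its list, with no reads in controls and 0.34 ± 0.12 FPKM.

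In the direct comparison of doses, lists of the translation machinery had higher means at 1500 µM than at 500 µM. Of 55 cytosolic ribosomal proteins 52 were higher, by a mean log2 difference of 0.80 (camera adjusted p = 2.66e-15). All 30 ribosome biogenesis factors were higher, by 0.99 (3.27e-05), as were all 11 mitochondrial ribosomal proteins, by 0.63 (0.00481), and 23 of 28 translation factors, by 0.39 (0.0102). The ribosome biogenesis protein Mak11 (CC77DRAFT_1019793) averaged 19.1 ± 6.61 FPKM against 6.69 ± 1.86 FPKM, and translation initiation factor 3 subunit I (CC77DRAFT_926567) 192 ± 35.9 FPKM against 90.8 ± 26 FPKM. These 4 were the lists past the threshold, and each had an adjusted p of 0.909 with an estimated correlation. No member passed over all genes or over the list alone. Ribosomal proteins at 1500 µM averaged 8.46 ± 0.40, and 1500 µM library 1 overlapped the libraries at 500 µM (exact permutation p = 0.2). For mitochondrial ribosomal proteins, ribosome biogenesis and translation factors the exact permutation p was 0.3, 0.4 and 0.4. Setting 500 µM libraries 1 and 2 with 1500 µM library 1 against the rest gave ribosomal proteins a camera adjusted p of 7.92e-21. This was smaller than with the labels, so the camera p does not tie the difference to dose. Without 1500 µM library 1 or without 500 µM library 3 the number of lists was 12, and without 500 µM library 1 it was 9. The mitochondrial ribosomal protein list did not pass without 500 µM library 2 (0.42). Translation factors did not pass without 1500 µM library 2 (0.20) or 3 (0.13), and differed by 0.85 without 1500 µM library 1. Ribosome biogenesis did not pass without 1500 µM library 3 (0.55), and differed by 0.56 without library 2 and 1.87 without library 1.

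Again edgeR called 0 of 11855 genes (smallest adjusted p = 0.15), with 1228 genes at an unadjusted p under 0.05, 615 higher and 613 lower at 1500 µM, where chance gives about 593. DESeq2 called 303 genes, 122 higher and 181 lower. The test first designed, limma on log2(FPKM + 1), called 3 genes at an adjusted p of 0.0497. They were CC77DRAFT_1021879, the bleomycin hydrolase gene below and a gene for a hypothetical protein. The last (CC77DRAFT_929381, 13.1 ± 7.70 FPKM at 1500 µM and 267 ± 82.0 FPKM at 500 µM) was named after its values were seen. The treatments did not overlap for 14.8% of genes, where chance gives 10%. The 8 genes taken by the rule had edgeR adjusted p of 0.15 or 0.178, not past the threshold, and were all among DESeq2's calls. Without 1500 µM library 3, 1 gene passed in edgeR.

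The NAD(P)-binding protein CC77DRAFT_1021879 averaged 128 ± 21.9 FPKM at 1500 µM against 19.9 ± 3.05 FPKM at 500 µM (log2 fold change 2.72, SE 0.38). The GroES-like protein CC77DRAFT_995685 averaged 46.9 ± 15.8 FPKM against 5.48 ± 2.55 FPKM (3.12, SE 0.52). The epoxide hydrolase-like gene CC77DRAFT_801013 averaged 175 ± 38.8 FPKM against 43.1 ± 4.02 FPKM (2.07, SE 0.36). Zinc finger protein OZF (CC77DRAFT_132578, NW_017306201.1, 145699 to 147564) averaged 101 ± 113 FPKM against 5.49 ± 2.08 FPKM (4.24, SE 0.76). Bleomycin hydrolase (CC77DRAFT_1020375, NW_017306199.1, 560369 to 562442), a cysteine protease, averaged 27.9 ± 6.48 FPKM against 187 ± 21.2 FPKM (-2.69, SE 0.41). A cytosolic Cu/Zn superoxide dismutase (CC77DRAFT_911584, NW_017306196.1, 671153 to 672099), which removes superoxide, averaged 7.04 ± 0.99 FPKM against 50.4 ± 5.58 FPKM (-2.80, SE 0.50). A clavaminate synthase-like gene (CC77DRAFT_970555, NW_017306209.1, 655072 to 656513) averaged 1.29 ± 0.12 FPKM against 8.69 ± 2.88 FPKM (-2.73). The dioxygenase CC77DRAFT_655232 averaged 1.32 ± 0.78 FPKM against 24 ± 8.38 FPKM (-4.13).

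Lists tied to stress, virulence and melatonin's precursor pathway did not pass by camera in any of the 3 comparisons on log2(FPKM + 1) with all libraries in at equal weight, and some passed in other settings. For antioxidant enzymes the adjusted p was 0.315 (500 µM against control), 0.736 (1500 µM against control) and 0.24 (1500 µM against 500 µM). For tryptophan and indole metabolism it was 0.92, 0.736 and 0.924, for plant cell wall degrading enzymes 0.2, 0.763 and 0.205, and for effector and virulence candidates 0.361, 0.736 and 0.823. For MAP kinase and cAMP signalling (20 genes) it was 0.998, 0.966 and 0.949. Without 1500 µM library 1 antioxidant enzymes were higher at 1500 µM than at 500 µM (camera adjusted p = 0.0102) and plant cell wall degrading enzymes lower (0.0131). The latter also passed with sample weights (0.0161) and without library 1 of both melatonin groups (0.00546, a setting chosen after the data were seen). Heat shock proteins and chaperones passed as higher at 1500 µM than at 500 µM without 1500 µM library 1 (0.000199), without 500 µM library 1 (0.00395) and with sample weights (2.19e-05). They passed as lower at 500 µM than in controls without control library 1 (0.0232) or 500 µM library 1 (0.0125). Secreted proteases and protease inhibitors (0.0533 between the doses with all libraries in) passed as lower at 1500 µM than at 500 µM in several settings, among them without 500 µM library 3 (0.00949), without 1500 µM library 1 (0.0148) and with quantile normalization (0.0465). Between the doses, single members were past the threshold over their list alone and not over all genes. These were a catalase-domain gene (CC77DRAFT_1097549, 9.74 ± 9.94 FPKM at 1500 µM against 0.54 ± 0.38 FPKM at 500 µM) and the superoxide dismutase among 41 antioxidant genes. Another was glutathione S-transferase II (CC77DRAFT_1032529, 541 ± 422 FPKM against 69.6 ± 18.6 FPKM). The gene of the major allergen Alt a 1 subunit (CC77DRAFT_941148) averaged 5232 ± 4165 FPKM against 652 ± 485 FPKM, with 4813 ± 4518 FPKM in controls. In the list of conidiation and spore markers, hydrophobin-like CC77DRAFT_1098293 averaged 2.20 ± 3.04 FPKM in controls, 0.23 ± 0.40 FPKM at 500 µM and 0.86 ± 1.35 FPKM at 1500 µM. Sporulation protein RMD8 (CC77DRAFT_973365) averaged 74.7 ± 14.9, 81.4 ± 31.4 and 75.8 ± 9.93 FPKM. Both were matched by product description only and do not show whether conidia differed between treatments.

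The log2 differences of the doses from the shared control correlated across genes with r = 0.30, where 100 simulations with no difference between groups gave a mean of 0.50 from the shared controls alone. The covariance was 0.216, against 0.342 in the simulations, and 58% of genes had the same sign at both doses, against 66.6%. Genes are not independent replicates, but the simulations drew them independently, so the simulated ranges are narrower than real libraries would give. Regrouping the 9 libraries gave 840 correlations with a median of 0.51 and a maximum of 0.791. Of these 747, the labels' own among them, were at least as large as with the labels. An agreement below what shared controls give is thus not shown. At an unadjusted p under 0.05, 34 genes were higher and 37 lower at both doses, where independent lists would share 5.9 and 8.8. In 100 simulations with no difference between groups the shared controls alone gave means of 87.4 and 36.9, from lists of other sizes (540 and 545 genes on average, against 936 and 369 here). Divided by the overlap of independent lists of the same sizes, the overlap was 5.74 (higher) and 4.22 (lower) here and 14.1 and 5.95 on average in the simulations (ranges 10.3 to 17.4 and 3.44 to 7.94). When the controls were split 1 against 2, so that the differences shared no library, the correlation was -0.288 to -0.02 over the 6 splits, a test chosen after the data were seen. With the scaling of all 9 libraries kept, the correlation was 0.055 without 1500 µM library 1, against a simulated mean of 0.448 with the same library left out. Without control library 1 it was 0.547 against 0.601, while the covariance was 0.603 against a simulated mean of 0.514 and maximum of 0.546. As genes were drawn independently, that maximum is no limit for real libraries.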

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

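DESeq2, counts divided by 4, other inputs to the list test, split controls and leaving out library 1 of both melatonin groups together were tried only after the data were seen. The test set beforehand for genes was limma on log2(FPKM + 1), which edgeR replaced although the counts were not raw. A 2-fold minimum can only remove calls, so its count of 0 was fixed in advance and is no sign of stability. The count of 0 genes in each comparison held under other filters, median ratio scaling, quantile normalization, no abundance trend and counts divided by 4. It changed with DESeq2 (118 genes at 500 µM against control, 28 at 1500 µM against control, 303 at 1500 µM against 500 µM). It also changed between the doses with sample weights (886 genes), with limma on log2(FPKM + 1) (3 genes) and with a pseudocount of 5 (3 genes), and at 500 µM against control with the 2 compared groups alone (2 genes). The cause was not tested. With each library left out in turn the counts ranged from 0 to 2, 0 to 2 and 0 to 1. Gene calls arose without control library 1 (2 genes in each comparison with control), 1500 µM library 2 (1 in each comparison with control) and 1500 µM library 3 (1, 2 and 1), and at 1500 µM against control without 1500 µM library 1 (1 gene). The number of lists fell from 8, 9 and 4 to 0, 0 and 0 with an estimated correlation, which by construction widens the error of lists whose members move together, and to 0, 0 and 0 with fry. The sample weights of the list test ran from 0.29 (1500 µM library 1) to 6.7 (1500 µM library 2). They gave 3 lists at 1500 µM against control and 9 between the doses. Without library 1 of both melatonin groups these were 4 and 9. Quantile normalization and genes with a mean of at least 1 FPKM each gave 7 lists between the doses. With each library left out, the lists ranged from 5 to 15, 2 to 10 and 4 to 12. At 1500 µM against control, the mean difference of amino acid synthesis reversed to 0.051 without 1500 µM library 1 and to 0.051 without library 1 of both melatonin groups, and ranged from -0.506 to 0.051 with each library left out. Over all settings the lists past the threshold gave 482 values, of which 93 were no longer past it and 2 reversed. For the cause of these changes no test was made. Correlation of the doses ranged from 0.061 to 0.545 with each library left out, and reversed to -0.01 without library 1 of both melatonin groups, where simulations with no effect gave means of 0.447 to 0.601 and of 0.4. It was -0.118 on average with the controls split, which by construction removes what shared controls add. The genes taken by rule kept their direction in all 575 values over the settings run, of which 34 passed the adjusted threshold. As the rule took only genes with non-overlapping groups and the smallest p, a change of direction was hardly possible. The kept direction is thus no sign of stability. Same-numbered libraries did not deviate together throughout (correlations of -0.29 to 0.53, over 0.1 in 2 of 9 pairs), so the numbers were not taken to pair them. Between control and 1500 µM these correlations were all above 0 (0.532, 0.073 and 0.229 for libraries 1 to 3), so a pairing there is not excluded. In the other comparisons they were 0.006 or lower. With the replicate block the genes called were 0 in each comparison and the lists 10, 9 and 4. The correlation of doses was 0.30, which a block cannot change when each treatment holds each library number once. In simulations of 500 µM against control, 20 of 50 genes changed 8-fold were called with depth divided by 4 and 20 with depth multiplied by 4, while 12 of 50 changed 2-fold were called with less spread and 0 with the spread as estimated.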

Other observations

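The tests of KEGG pathways, acetyl unit genes, library scaling, depth and exchanged labels were chosen only after related values were seen, and how the tests of depth, exchanged labels and acetyl unit genes were made or read was revised after their values were seen. By camera with the preset correlation, 14 of 102 KEGG pathways passed at 500 µM against control, 13 lower and 1 higher, 7 at 1500 µM against control, all lower, and 8 between the doses, 7 higher at 1500 µM and 1 lower. None passed with an estimated correlation (smallest adjusted p of 0.89, 0.98 and 0.985). At 500 µM the ribosome pathway differed by a mean log2 of -0.93 (121 of 131 genes lower) and oxidative phosphorylation by -0.49 (69 of 87 lower). The spliceosome differed by -0.27 and selenocompound metabolism by -0.91 (12 of 12 lower), while the yeast MAPK signalling pathway was higher by 0.19. Pathways close to the lists higher at 500 µM did not pass, namely fatty acid degradation (camera adjusted p = 0.295), peroxisome (0.331) and nitrogen metabolism (0.795, 13 genes higher and 13 lower). At 1500 µM DNA replication differed by -0.35 (44 of 50 lower) and mismatch repair by -0.34 (29 of 32 lower). The peroxisome pathway did not pass and had a mean of the sign opposite to the fatty acid oxidation and peroxisome list (-0.04, 61 of 113 lower, 0.805), and steroid biosynthesis (0.357) and fatty acid biosynthesis (0.247) did not pass either. Between the doses, RNA polymerase genes were higher at 1500 µM by 0.57 and the citrate cycle was lower by -0.37.

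Another 5 genes of acetyl unit use had mixed values at 500 µM, none past the adjusted threshold (adjusted p of 0.556 to 0.879 in edgeR). Isocitrate lyase (log2 fold change 3.12, SE 0.80), malate synthase (2.25, SE 0.56) and acetate-CoA ligase CC77DRAFT_331045 (1.92, SE 0.62, 429 ± 252 FPKM against 113 ± 54.7 FPKM) had higher values. The mitochondrial carnitine carrier CC77DRAFT_994655 had lower values (16 ± 4.10 FPKM against 32.3 ± 24.4 FPKM), and acetyl-coenzyme A synthetase CC77DRAFT_931441 was near 0 in all groups. At 1500 µM isocitrate lyase averaged 499 ± 233 FPKM and malate synthase 194 ± 50.8 FPKM.

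Gluconeogenic and peroxisomal genes with higher values at 500 µM prompted the hypothesis that the hyphae may have used more acetate and fatty acids. The 5 genes above were picked by product description before their own values were seen, but after the lists that hold isocitrate lyase, malate synthase and the carnitine carrier had been seen to have higher means. Over the 5 genes the mean log2 difference from controls was 1.28, with each 500 µM library above each control library (exact permutation p = 0.1, the smallest possible), but this rests largely on isocitrate lyase and malate synthase and so does not test the hypothesis. Over the 3 genes outside the list of the tricarboxylic acid and glyoxylate cycles the mean was 0.351 (SE 0.106), which leaves the hypothesis open. A difference in growth stage or nutrient supply between the cultures was not tested.

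Lower ribosomal protein transcripts at 500 µM could reflect the treatment or technical differences. A scale factor per library as the whole cause is argued against, since the ribosomal mean less the median gene of each library differed by -1.064 (95% interval -1.90 to -0.23), and so are unequal distributions of values, since after quantile normalization it differed by -0.914 (-1.62 to -0.20). Loss of short or abundant transcripts remains open for part of the pattern, since non-ribosomal genes matched on length and abundance had a median difference of -0.339 (SD 0.14 over draws) against -1.18 for ribosomal proteins. Depth within treatments predicted a difference of 0.07 (SE 0.305), of the opposite sign, but with depth as a term beside treatment the difference of -1.172 had a 95% interval of -2.39 to 0.05, which reaches 0 and leaves depth open. Growth state, which sets ribosomal protein expression in fungi, was not tested and stays open beside the treatment.

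The placing of libraries across treatments on the first principal component could come from depth, from exchanged labels or from other differences between samples, biological or technical. Depth as the whole cause is argued against: libraries next to each other in depth lay 64.6 apart on average, 2.981 times as far as in a component that follows the order of depth (2.35 to 2.98 with each library left out), and 1500 µM libraries 1 and 2, of nearly equal depth, lay at -87.5 and 53.9. For depth as part of the cause, Spearman's rho with the component was 0.267 over 9 libraries (exact permutation p = 0.493, Pearson r = 0.21, exact permutation p = 0.566, r = 0.06 without the 2 libraries of most extreme depth), and this stays open since the upper 95% limit of rho was 0.79. The split with the highest pseudo-F (1.97) of all 280 needs 4 libraries to move from the labels, while the best exchange of 1 pair reached 1.90 against 1.20 for the labels. As the labels themselves explain little, a true grouping need not rank first. An exchange of labels thus cannot be told apart from spread between samples, which may be technical.

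Splits of the libraries were counted for each comparison. Counts of splits with at least as many genes or lists, or with the ribosomal list past the threshold, include the split of the labels. For any difference among the 3 groups, 24 of 100 drawn splits gave as many genes at an unadjusted p under 0.05 as the labels (930 genes, highest other 2325), so chance cannot be excluded. Of the other splits drawn, 18 called genes past the adjusted threshold, up to 235, where the labels called 0. Whether a structure of the libraries other than treatment underlies this was not tested. At 1500 µM against control, another split of the 6 libraries called 33 genes. The ribosomal protein list passed by camera in 6 of the 10 splits in each comparison. With 6 libraries there are 10 splits, too few for a share under 0.05. At 500 µM against control 3 splits gave at least as many such genes (936, highest other 1318) and 4 as many lists (8, highest other 14). At 1500 µM against control these were 7 (369, highest other 2361) and 6 (9, highest other 16), and between the doses 2 (1228, highest other 1887) and 8 (4, highest other 19).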
